A study of Schizosaccharomyces pombe with 5 samples.

How the data were processed

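Cells were grown at 30 °C and cross-linked at 18 °C for 30 min, per the labels. DNA immunoprecipitated with an antibody against H3K9me2 was labelled with Cy5 and whole-cell-extract DNA with Cy3, and both were hybridised to custom Agilent arrays of 60-nucleotide probes that tile the genome at a median spacing of 300 bp. The 5 arrays fell into 3 groups by genotype, wt with 2 arrays, rrp6Δ with 2 and alp13Δ rrp6Δ with 1. No dyes were swapped, so a dye effect common to all arrays is in every ratio and cancels only between groups.

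Per the file headers, the authors' scanner files came from Feature Extraction 8.5.1.1 and hold an intensity per spot and dye; no background was subtracted, no surrogate values were used, and the dyes were normalized with a linear factor and LOWESS. The deposited LogRatio column was log10 of the processed Cy5 over Cy3 intensity, as the values showed. The authors' value table was found to be log2 of the Cy5 over Cy3 median spot signal plus a constant for each array, with no LOWESS. Its column medians were 0.01, 0, 0, 0.04 and -0.01; why those constants were chosen stays unknown. It served as an alternative.

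The genome build behind the probe design was not stated, so the probe sequences were matched exactly to the reference assembly ASM294v3. Of 41551 probes, 40396 matched once, 1053 several times and 102 nowhere. The 2447 probes with an outlier flag on any array were left out, which left 39104; saturated probes (21 on any array) were kept. In Cy3, 2 probes were not well above background on some array. The log2 ratio of processed Cy5 over Cy3 was centred on each array's median. A gene's value was the mean over its probes (5 at the median), for 5078 of 5113 annotated protein-coding genes, and probes that match several places counted in each.

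The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 5 arrays in 1 fit of 3 groups, 2 residual degrees of freedom and no block. The double mutant's lone array was assumed to vary like the other groups. The same fit was made for genes, for probes and for the means of 31 lists, each with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333 and was not used. Sets were tested with camera, at a preset correlation of 0.01 and at an estimated one, and with fry. The list means of the subtelomeric helicases, the mating-type genes and Tf2 rest on shared probes. Domains were runs of at least 4 probes, with gaps of 1 probe and 2 kb allowed, whose 3-probe running median was at least 1 (log2) in every array of the strain. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

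The arrays were scanned on 2 days: replicate 1 of wt and rrp6Δ on day 1, and the other 3 arrays on day 2. Scan day was therefore fitted as a block, with 1 residual degree of freedom, and differences were also taken within each day. The correlation of the log2 ratio with GC content was -0.10 and -0.14 on day 1 and 0.25, 0.21 and 0.21 on day 2. It was taken over 37642 probes that match once, outside the centromeres, mating-type region, chromosome ends and long terminal repeats.

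The tests, lists, domain rule, the rule for named genes and most alternatives were fixed before the data were examined. The text names rrp6 and alp13; per comparison, the 10 genes with the largest difference in each direction among genes with at least 2 probes and no overlap between groups, calls first; and up to 4 members of each list. No gene passed the threshold, so the named genes are given as values. The list members mcp7 and num1 come under the last part, and man1 and nab2 were named after their domain was seen. Chosen after the data were seen were the lists of probes without a match, long non-coding RNA genes in place of protein-coding genes, list shifts from probes that match once, the limit of 0.5 for a level to count as methylated and the limit of 0.25 for list differences followed through the alternatives.

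The calling was tested on simulated data with 200 changed genes. A change of 1 (log2) was recovered in 75.2% of genes for rrp6Δ against wt and 54.8% for the double mutant, a change of 0.5 in 4.8% and 1.2%, with means of 7 and 5.8 false calls. The simulated arrays were independent and had no scan-day effect, so these shares may not hold for the real arrays. This was the second version of the simulation. The first drew its noise from the shrunken variances and recovered more; it was replaced because the fitted prior has a heavier spread. Alternatives were normexp background correction (offset 50), loess, quantile normalization, centring on the mode or on euchromatic probes, the value table, filters on dim, saturated or sparse probes, a median per gene, blocks, other eBayes settings, and leaving out each replicate.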

Results

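Dimethylation of histone H3 at lysine 9 (H3K9me2), the mark of fission yeast heterochromatin, was measured by chromatin immunoprecipitation on tiling arrays (ChIP-chip) in 3 strains of Schizosaccharomyces pombe. Wild type (wt) had 2 arrays, rrp6Δ had 2, and the double mutant alp13Δ rrp6Δ had 1. Rrp6 is a nuclear exonuclease of the RNA exosome, and Alp13 is a chromodomain subunit of a Clr6 histone deacetylase complex. Each array set Cy5-labelled immunoprecipitated DNA against Cy3-labelled whole-cell-extract DNA, so a log2 ratio above 0 means enrichment over the array's median. The median spot signal was 979 to 1268 in Cy3 and 812 to 1276 in Cy5, against 332 to 343 and 289 to 306 at the negative control spots. The number of arrays limits the precision. Nothing in the labels says that replicate arrays came from separate cultures, so each adjusted p measures the spread between these samples. Values are means ± SD over n = 2 arrays for wt and rrp6Δ; the double mutant had no replicate. Over all kept probes, the log2 ratio correlated at -0.05 between the 2 rrp6Δ arrays and 0.36 between the 2 wt arrays. Replicate 2 of rrp6Δ correlated at 0.75 with replicate 2 of wt and 0.63 with the double mutant, all scanned on the same day. Replicate arrays of rrp6Δ therefore did not agree across the genome. Positions refer to the reference assembly ASM294v3.

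The whole-cell-extract channel was read first as a check of the genotypes. At rrp6 (I 610848 to 613338, 7 probes) the Cy3 signal, as log2 relative to the array median, was -1.69 and -1.96 in rrp6Δ and -1.93 in the double mutant, against 0.30 and 0.37 in wt. At alp13 (I 1587022 to 1588577, 4 probes) it was -1.56 in the double mutant and between -0.23 and 0.05 in the other 4 arrays. The low signals lay in the arrays whose labels name each deletion. At the marker gene ura4 it was -0.64 and -1.29 in rrp6Δ, 0.04 in the double mutant and -0.06 and -0.19 in wt. In the ChIP over whole-cell-extract ratio, rrp6 differed from wt by 0.11 ± 0.09 (SE) in rrp6Δ and by 0.12 ± 0.11 (SE) in the double mutant, and alp13 by 0.11 ± 0.12 (SE) and 0.05 ± 0.14 (SE). In an array that lacks rrp6 or alp13, the probes of that gene lack their target DNA. The ratio there sets background against background and says nothing about H3K9me2. Neither gene was called in any comparison (limma, adjusted p = 1.0).

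**Figure D1:**
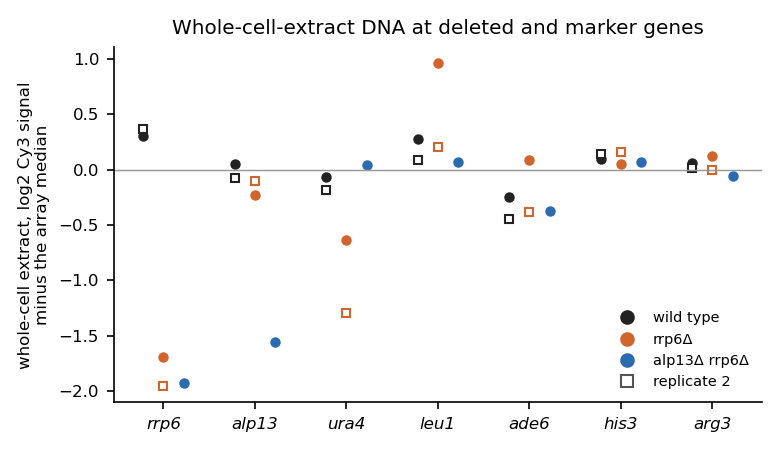
Whole-cell-extract signal (log2 Cy3 signal minus the array median, y axis) at 7 genes (x axis), 1 point per array, with replicate 2 as open squares. At rrp6 the 3 mutant arrays sit between -1.69 and -1.96, and at alp13 the double mutant sits at -1.56.

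In wt, H3K9me2 lay at the centromeres, the subtelomeres, a mating-type sequence shared by 2 genes and a few meiotic genes. Centromeres 1, 2 and 3 had mean log2 ratios of 1.17 ± 0.20, 1.25 ± 0.21 and 1.42 ± 0.26. Subtelomeres 1L, 1R and 2R had 0.99 ± 0.20, 1.23 ± 0.26 and 1.01 ± 0.30, and subtelomere 2L had 0.42 ± 0.26. The paired subtelomeric helicase genes tlh1 and tlh2 had 1.29 ± 0.16. Of the mating-type genes, 2 of the 4 listed were measured, mat1-Mc and mat3-Mc. They carry the same sequence and read 1.07 ± 0.09, so the arrays cannot tell which of them carried the mark. The mating-type region as a whole (136 probes) read 0.25 ± 0.06. The 25 mating-type contig probes that match nothing in the reference, a list added after the data were seen, read 1.34 ± 0.26. Among 10 meiotic genes whose transcripts are removed through the RNA-binding protein Mmi1, mei4, ssm4 and mcp7 were at least 0.5 in both wt arrays. As background, all other unique probes had 0.01, and mitochondrial DNA, which carries no histones, had -1.47 ± 0.75. The mitochondrial level depended on the kind of ratio. In replicates 1 and 2 of wt it was -0.37 and -0.95 with normexp, and -0.04 and -0.50 in the authors' value table.

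In rrp6Δ the same regions read 0.70 ± 0.17, 0.70 ± 0.14 and 0.79 ± 0.13 at centromeres 1 to 3, and 0.40 ± 0.07, 0.45 ± 0.09, 0.16 ± 0.22 and 0.34 ± 0.03 at subtelomeres 1L, 1R, 2L and 2R. In the double mutant the centromeres read 1.21, 1.24 and 1.40, the helicases 1.49 and the mating-type genes 1.11. Its subtelomeres 1L, 1R, 2L and 2R read 0.42, 0.15, -0.11 and 0.35. Each of these is a mean over 40 kb, and domains near some chromosome ends stayed above 1, as given below. With only probes that match the genome once, subtelomere 2L in wt read -0.05, and subtelomere 2R read -0.01 in rrp6Δ and -0.15 in the double mutant, so the levels there rested on probes that match several places.

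**Figure D2:**
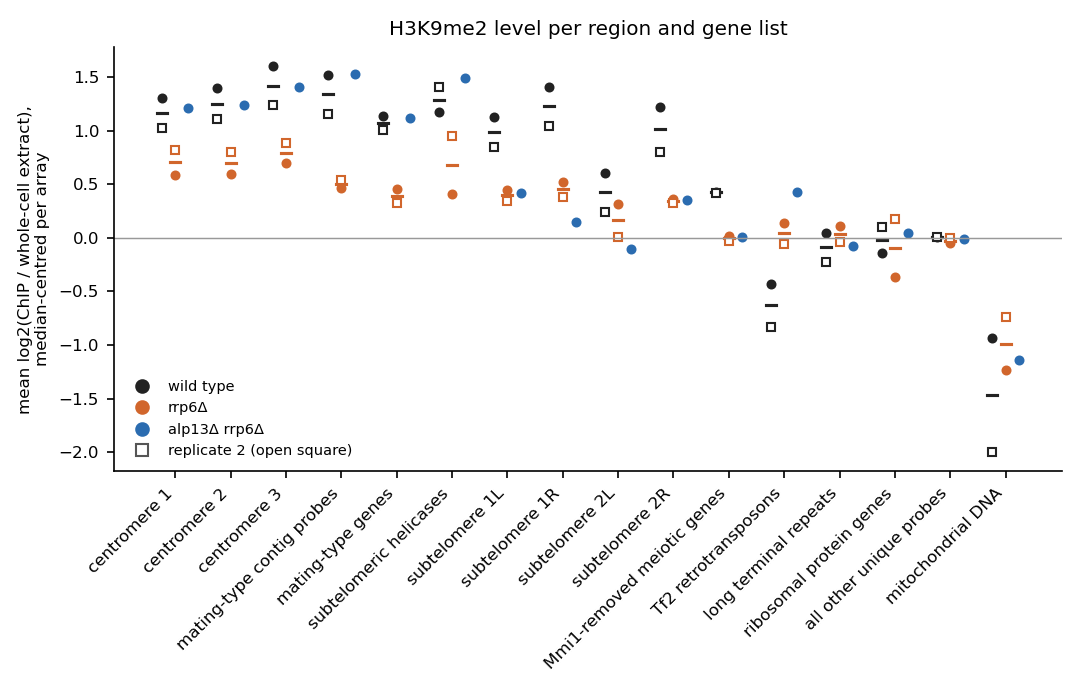
Mean log2 ratio of ChIP over whole-cell extract (y axis) of 16 regions or gene lists (x axis), 1 point per array, with replicate 2 as open squares and bars at the means of wt and rrp6Δ. Centromere 1 sits at 1.30 and 1.03 in wt, 0.58 and 0.82 in rrp6Δ and 1.21 in the double mutant, and quantile normalization reversed the order of wt and rrp6Δ at the centromeres.

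Runs of enriched probes, with a log2 ratio of at least 1 in every array of a strain, described the extent of the mark. Wild type had 20 such domains that covered 175.2 kb, and 24 domains of the double mutant covered 144.4 kb, of which 22 overlapped a wt domain. A probe that matches several places counted at each place, so repeats enter these counts and lengths more than once. The wt domains at mat1-Mc and mat3-Mc, for example, had identical means in all 5 arrays. The longest wt domain outside the centromeres covered 28.6 kb of the right end of chromosome I (5529535 to 5558137), with mean log2 ratios of 1.82 and 1.60 in wt, 0.54 and 0.46 in rrp6Δ and -0.06 in the double mutant. Nearer that end, a domain of the double mutant at 5577214 to 5579096 read 1.48, against 1.40 and 1.41 in wt. Its domain at 5575158 to 5576223 read 1.29, against 1.78 and 1.91. A domain at II 4519985 to 4521050 had identical means in all 5 arrays. The arrays therefore cannot tell which of these 2 chromosome ends kept that signal. The double mutant's domains over tlh1 (I 443 to 10508) and tlh2 (II 4522041 to 4532104) read 1.45 and 1.45. In wt both read 1.27 and 1.36, but these genes share probes. A domain in ssm4 (I 4535094 to 4535960) was called in wt, at 1.31 and 1.29, and had 0.17 and 0.01 in rrp6Δ and 0.15 in the double mutant. A domain over man1 and nab2 (I 5236056 to 5238969) was called in the double mutant, at 1.07, against 0.42 and 0.56 in rrp6Δ and 0.09 and 0.23 in wt. The rule gave 0 domains in rrp6Δ, where centromere ratios lay close to the threshold: its replicate 1 alone gave 0 and its replicate 2 alone gave 35, and a threshold of 0.8 gave 25. The double mutant had no second array that had to pass, and no error rate belongs to these counts. Taken singly, replicate 1 of wt gave 32 domains (221.3 kb) and replicate 2 gave 22 (181.5 kb).

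**Figure D3:**
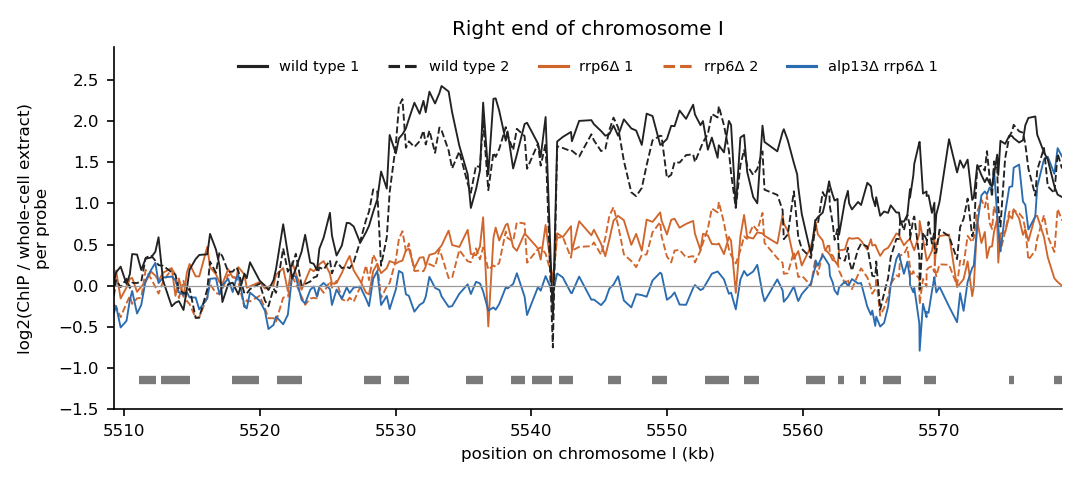
Log2 ratio of ChIP over whole-cell extract per probe (y axis) along the right end of chromosome I (x axis, kb), 1 line per array, with protein-coding genes as grey bars. Over the 28.6 kb domain the means were 1.82 and 1.60 in wt, 0.54 and 0.46 in rrp6Δ and -0.06 in the double mutant.

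The comparison of rrp6Δ with wt asks where H3K9me2 differs in the strain without the exosome nuclease. The largest differences to the low side were in a block of genes next to the right end of chromosome I: SPAC186.02C had -1.47 ± 0.12 (SE) on the log2 scale, gdt1 had -1.24 ± 0.10, SPAC186.06 had -1.22 ± 0.11 and pdc102, a pyruvate decarboxylase gene, had -1.16 ± 0.18. SPAC186.04C, SPAC186.07C, SPAC186.08C and, at the left end of the chromosome, SPAC212.08C lay between -1.12 and -1.06. Of the meiotic genes, mei4, which encodes a forkhead transcription factor of meiosis (II 1473068 to 1475285), had -1.02 ± 0.12, and ssm4 (I 4534674 to 4536736) had -1.02 ± 0.10. The largest differences to the high side were 10 copies of the retrotransposon Tf2, between 0.67 and 0.68.

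By group, 9 of the 10 meiotic genes lay lower in rrp6Δ and 1 higher, with a list mean of -0.43 ± 0.08 (SE, limma adjusted p = 0.098). The examples mei4 and ssm4 are given above, mcp7 had -0.92 ± 0.15 and num1 (mcp5 in the list) had -0.61 ± 0.11. None of the 10 was called over all genes, and 5 passed when adjusted over the list alone. Fry, which tests whether a set moves one way on balance, gave adjusted p = 0.025, and adjusted p = 0.127 with scan day as a block. Camera gave the list adjusted p = 0.255 with an estimated correlation. The 13 Tf2 copies all lay higher (list mean 0.67 ± 0.18 SE, limma adjusted p = 0.098; 0.27 in the authors' value table), but they share almost all of their probes, so they are close to 1 measurement; none was called over all genes and 13 passed when adjusted over the list alone. The helicases tlh1 and tlh2 (list mean -0.61 ± 0.23 SE, adjusted p = 0.168) and the 2 mating-type genes (-0.68 ± 0.11 SE, adjusted p = 0.098) also share probes within each list, and 2 of 2 passed in each list when adjusted over the list alone. The helicase difference was -0.76 within day 1, -0.46 within day 2 and -0.34 without replicate 1 of rrp6Δ, and quantile normalization reversed it to 0.13.

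**Figure D4:**
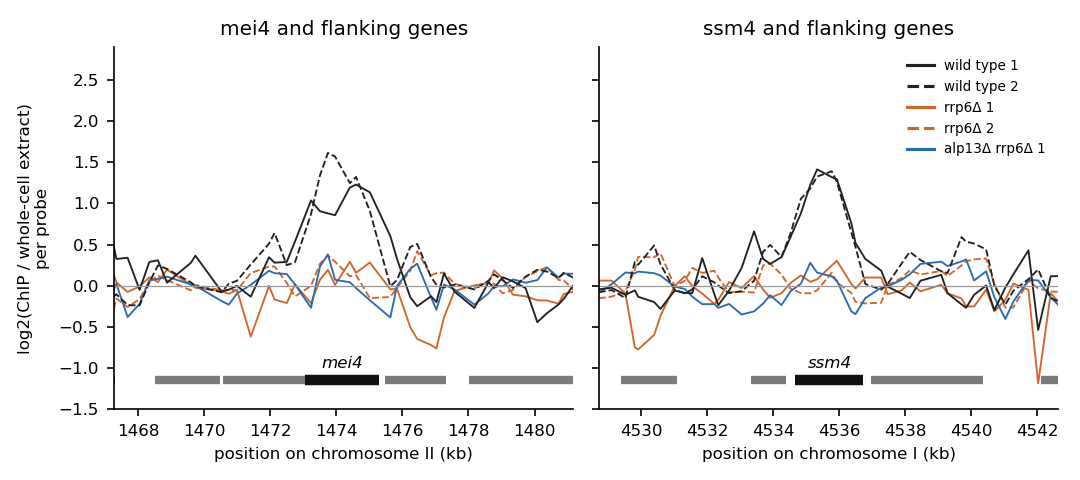
Log2 ratio of ChIP over whole-cell extract per probe (y axis) around mei4 and ssm4 (x axes, kb), 1 line per array, with the named gene in black and its neighbours in grey. As gene means, mei4 had 1.03 and 1.27 in wt, 0.11 and 0.14 in rrp6Δ and 0.04 in the double mutant.

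Among the regions, subtelomeres 1R, 2R and 1L differed between rrp6Δ and wt by -0.78 ± 0.16 (SE), -0.67 ± 0.17 and -0.59 ± 0.14 (limma, adjusted p = 0.098 each). Centromeres 1, 2 and 3 differed by -0.46 ± 0.16, -0.56 ± 0.15 and -0.63 ± 0.17 (adjusted p = 0.142, 0.098 and 0.098), and quantile normalization reversed these to 0.22, 0.14 and 0.16. With only probes that match the genome once they were -0.17, 0.026 and -0.11, so centromere 2 changed sign there. Paired domains at centromere 1 read almost alike in replicate 1 of wt (2.18 and 2.18), so they may share probes. Probes that match once leave out such shared sequence, which may be much of the methylated centromere DNA, and cannot decide whether it changed. Within scan day 1 and scan day 2 the differences were -0.89 and -0.66 at subtelomere 1R, -0.72 and -0.20 at centromere 1, 0.57 and 0.77 at Tf2, and -0.41 and -0.45 over the meiotic genes. With scan day as a block the adjusted p was 0.089 at subtelomeres 1L, 1R and 2R, at Tf2 and at the meiotic genes, and between 0.172 and 0.213 at the centromeres. The mating-type region differed by -0.29 ± 0.09, and subtelomere 2L by -0.26 ± 0.19. The latter was -0.021 with probes that match once, and when a replicate was left out it ranged from -0.44 (without replicate 2 of wt) to -0.08 (without replicate 1 of wt). The mating-type contig probes that match nothing in the reference, a list added after the data were seen and not fitted by limma, differed by -0.84 (-1.06 on day 1 and -0.62 on day 2), and the subtelomeric clone probes without a match by -0.51 (-1.03 and 0.012). Mitochondrial DNA differed by 0.48 ± 0.44, with -0.30 on day 1 and 1.26 on day 2, and was -0.057 in the authors' value table and -0.052 without replicate 2 of wt. The rRNA genes differed by -0.28 ± 0.35, with -0.81 on day 1 and 0.26 on day 2, and by 0.19 without replicate 1 of rrp6Δ.

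The other gene lists had small differences: exosome genes 0.02, heterochromatin factors 0.005, Clr6 complexes 0.01, phosphate genes 0.01, stress genes 0.03, ribosomal protein genes -0.08 and strain markers -0.10. Histone genes, snoRNA genes and the 3 kinds of intergenic probes lay between -0.10 and 0.001, tRNA genes at 0.17, long terminal repeats at 0.12, and the left and right ends of chromosome III at -0.18 and -0.11. The left end had -0.76 on day 1 and 0.39 on day 2, and the right end -0.49 and 0.27.

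No gene of 5078 was called by limma for rrp6Δ against wt (smallest adjusted p = 0.112; 85 genes at an unadjusted p under 0.05), no probe of 39104 (908 probes) and no list of 31 (10 lists). With scan day as a block, which here equals the replicate number, 19 genes were called, all of them lower in rrp6Δ, of which 13 lay within 100 kb of a chromosome end, and 395 probes, of which 23 were higher. Without replicate 1 of rrp6Δ 8 genes were called, and 78 without replicate 2. Each of those fits left 1 rrp6Δ array and took its spread from wt alone. With all arrays kept, the arrays of the groups did not overlap at 24.97% of genes. Chance gives 33.3% for exchangeable arrays, which these are not, since the deviations of same-day arrays from their group means correlated at 0.59 across genes; the same holds for the shares in the other comparisons. Camera called 4 gene lists and 15 probe lists with its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.255 for gene lists and 0.181 for probe lists.

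The comparison of alp13Δ rrp6Δ with wt asks the same of the double mutant. The block at the right end of chromosome I again held the largest differences to the low side: SPAC186.07C had -1.88 ± 0.12 (SE), SPAC186.02C -1.83 ± 0.14, SPAC186.06 -1.76 ± 0.13 and pdc102 -1.72 ± 0.23. SPAC186.08C, gdt1, SPAC186.04C, SPAC186.03, SPAC750.01 and the chromosome II gene SPBPB21E7.09 lay between -1.70 and -1.12. To the high side, SPAC14C4.04 (I 5234060 to 5235661), next to the man1 and nab2 domain, had 1.09 ± 0.16, and 9 Tf2 copies lay between 1.05 and 1.07.

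By group, 8 of the 10 meiotic genes lay lower and 2 higher, with a list mean of -0.42 ± 0.10 (SE, limma adjusted p = 0.185); mei4 had -1.11 ± 0.14, ssm4 -1.06 ± 0.13 and mcp7 -1.01 ± 0.18. None was called over all genes and 5 passed when adjusted over the list alone. Fry gave adjusted p = 0.039, and 0.189 with scan day as a block, and camera gave adjusted p = 0.354 with an estimated correlation. The 13 Tf2 copies had a list mean of 1.06 ± 0.22 (adjusted p = 0.163; 1.26 within day 2 and 0.68 in the value table), and 13 passed when adjusted over the list alone. The helicases differed by 0.20 ± 0.28 (0.088 within day 2) and the mating-type genes by 0.05 ± 0.13, with 0 of 2 past the threshold in each.

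Subtelomere 1R differed between the double mutant and wt by -1.08 ± 0.20 (limma, adjusted p = 0.163), and subtelomeres 1L, 2L and 2R by -0.57 ± 0.17, -0.53 ± 0.24 and -0.66 ± 0.21. Within day 2, the only day that holds the double mutant, these were -0.90, -0.43, -0.35 and -0.45, and with probes that match once -1.66, -1.10, -0.13 and -0.80. Centromeres 1, 2 and 3 differed by 0.04 ± 0.19, -0.01 ± 0.19 and -0.02 ± 0.21, and the mating-type region by -0.02 ± 0.12. The probes without a match differed by 0.18 for the mating-type contig (0.37 within day 2) and -0.92 for the subtelomeric clones (-0.52 within day 2). The mitochondrial difference was 0.33 ± 0.53 and 0.86 within day 2, and turned to -0.052 with normexp, -0.15 in the value table and -0.20 without replicate 2 of wt. The other gene lists lay between -0.10 and 0.07, and the other probe lists between -0.27 and 0.04. The lowest of these were the left and right ends of chromosome III, -0.26 and -0.27, with -0.05 and -0.10 within day 2.

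No gene was called by limma for the double mutant against wt (smallest adjusted p = 0.071; 116 genes at an unadjusted p under 0.05), no probe (824) and no list (5). With scan day as a block 30 genes were called: 13 higher, which were the 13 Tf2 copies, and 17 lower, of which 14 lay within 100 kb of a chromosome end and 13 were also called lower in rrp6Δ. That block also called 169 probes, of which 51 were higher. The groups did not overlap at 58.0% of genes, where chance gives 66.7% for exchangeable arrays. Camera called 2 gene lists and 15 probe lists with its preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.354 and 0.425).

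The comparison of alp13Δ rrp6Δ with rrp6Δ asks what differs when Alp13 is also lost. The whole-cell-extract signal at ura4 also differed (-0.64 and -1.29 in rrp6Δ, 0.04 in the double mutant). No array held alp13Δ alone, so differences here cannot be assigned to Alp13. Higher in the double mutant were mae2 (III 275261 to 277262) at 1.18 ± 0.34 (SE), SPAC750.08C at 1.16 ± 0.30, tlh1 and tlh2 at 0.81 ± 0.25, and mat1-Mc and mat3-Mc at 0.72 ± 0.13. The gene per1 beside centromere 1 had 0.65 ± 0.16. The genes eft201, rpl802 and rpl803 had 0.70 ± 0.58, 0.67 ± 0.53 and 0.66 ± 0.55, and within day 2 0.02, 0.05 and 0.04. Lower were SPAC186.07C at -0.76 ± 0.12, SPAC186.08C at -0.63 ± 0.14, SPBPB2B2.18 at -0.63 ± 0.42, pdc102 at -0.56 ± 0.23, SPAC977.18 at -0.54 ± 0.45 and SPAC186.06 at -0.54 ± 0.13. Within day 2, SPBPB2B2.18 had -0.36 and SPAC977.18 -0.28. Beyond these, SPBC1348.01, SPBC1348.09, ayr2 and SPBCPT2R1.04C lay between -0.53 and -0.47, with SPBC1348.01 at -0.36 within day 2.

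Centromeres 1, 2 and 3 differed between the mutants by 0.51 ± 0.19, 0.55 ± 0.19 and 0.61 ± 0.21 (limma, adjusted p = 0.384, 0.373 and 0.373), which quantile normalization reversed to -0.03, -0.03 and -0.05; within day 2 they were 0.39, 0.44 and 0.52, and with probes that match once 0.32, 0.012 and 0.14. The helicases differed by 0.81 ± 0.28 (adjusted p = 0.373; 0.54 within day 2) and the mating-type genes by 0.72 ± 0.13 (adjusted p = 0.205; 0.79 within day 2), and in each list 2 of 2 passed when adjusted over the list alone and 0 over all genes. The mating-type region differed by 0.27 ± 0.12 and the mating-type contig probes without a match by 1.02. Subtelomeres 1L, 1R, 2L and 2R differed by 0.02 ± 0.17, -0.30 ± 0.20, -0.27 ± 0.24 and 0.01 ± 0.21, and within day 2 by 0.07, -0.24, -0.11 and 0.03. The meiotic genes differed by 0.01 ± 0.10, with 6 higher and 4 lower, and Tf2 by 0.38 ± 0.22. The subtelomeric clone probes without a match differed by -0.41. The other lists lay between -0.15 and 0.14.

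No gene was called by limma between the mutants (smallest adjusted p = 1.0; 32 genes at an unadjusted p under 0.05), no probe (324) and no list (4). With scan day as a block the counts were also 0, with 90 genes, 705 probes and 3 lists at an unadjusted p under 0.05; without replicate 2 of rrp6Δ 476 probes were called. The fit without replicate 2 of rrp6Δ set 1 double-mutant array against 1 rrp6Δ array from the other scan day, with its spread from wt alone. With all arrays kept, the groups did not overlap at 54.6% of genes, where chance gives 66.7% for exchangeable arrays. Camera called 4 gene lists and 17 probe lists with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.4996 and 0.2802).

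The changes of the 2 mutants against wt correlated across 5078 genes with Pearson's r of 0.68, but with 0.38 when replicate 1 of rrp6Δ stood alone and 0.73 when replicate 2 did. Both changes use the same wt arrays, and unchanged groups of the same sizes against shared controls gave 0.41 in 100 simulations. The simulation drew the arrays as independent and left out scan day, although same-day deviations correlated at 0.59, so it does not show how much of 0.68 the mutants share. Between pairs that share no array, r was 0.49 for rrp6Δ against wt on day 1 with the double mutant against wt on day 2, and 0.32 for rrp6Δ against wt on day 1 with the same on day 2. Genes are not independent replicates, so no p belongs to these values.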

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

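The tests below were chosen after the result they measure was seen, except the 2 on whole-cell-extract signal (at the meiotic genes and at Tf2), which were written before.

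In the whole-cell-extract channel, which the comparisons of ChIP ratios do not use by itself, 7 of 41 regions and genes were higher in all 3 mutant arrays than in both wt arrays, and 9 were lower, a side counted after the values were known. The lower ones were rrp6, alp13, SPAC14C4.04, mei4, Tf2-1, the Tf2 list and centromeres 1, 2 and 3, where the gap from the highest mutant array to the lowest wt array was -0.042, -0.064 and -0.027. For the higher ones the gap between the lowest mutant array and the highest wt array (log2) was 0.32 at the rRNA genes, 0.29 and 0.30 at the left and right ends of chromosome III, 0.11 at snoRNA genes, 0.048 and 9.4e-05 at intergenic probes of convergent and tandem genes, and 0.014 at mae2. Chance would place 10% of items on each side, or 4.1 of 41, and the items overlap. A margin of 0.5 was set first and picked 0 items, and a margin of 0.25, tried after the values were known, picked 3; the margin was then dropped, so the 7 items come from the third version of this rule. With normexp background correction 5 of 41 items were lower, none of them a centromere, and 13 were higher, the subtelomeres, the mating-type region and tRNA genes among them, and the margin of 0.5 picked 3: 0.58 at the left end of chromosome III, 0.55 at the right end and 0.58 at the rRNA genes.

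At the rRNA genes, the Cy3 signal was 4.19 and 2.97 in rrp6Δ, 3.54 in the double mutant and 2.17 and 2.65 in wt. No explanation was tested.

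The lower ratios of mei4, ssm4 and mcp7 in both mutants were set against 3 technical explanations. If the mutant arrays were enriched less as a whole, these genes would keep the same share of the wt excess as the centromeres; the lowest centromere share exceeded the highest gene share by at least 15.9 percentage points in all 3 same-day pairs and 3 kinds of ratio. Methylated regions did not keep a common share, so the margin depends on the region chosen. In the double mutant, subtelomere 1R kept 10.2, 5.3 and 11.6% (processed, normexp, value table) against 1.8, 1.7 and 2.5% at mei4, the highest of the genes. A higher whole-cell-extract signal does not account for the lower ratios at these genes, since the largest same-day difference in Cy3 was 0.13. Nor does scan day, since the same-day difference closest to 0 was -0.84. A loss of the mark at these genes without Rrp6 may therefore be biological, as a hypothesis found and tested on the same arrays, in genes picked for a level of 0.5 or more in both wt arrays.

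The lower ratios of the centromeres in rrp6Δ may reflect lower enrichment of those arrays as a whole. A first version of that test compared the mean centromere share with the highest share of other methylated regions in processed ratios, and put the centromeres outside by 0.55 points on day 1 and 10.4 points on day 2. It ignored the spread between centromeres and other kinds of ratio and was replaced after its result was seen; in the second version the lowest centromere share minus the highest other share went down to -6.30 points, on day 1 in the value table. On day 1 the shares overlapped in all 3 kinds of ratio. On day 2 every centromere lay above every other region in all 3, with lowest centromere shares of 62.1, 54.2 and 43.1% against 56.5, 42.6 and 38.7%, so the days differ and the data do not decide. LOWESS is argued against as the source, since the mean difference was -0.86 in the value table, which has none. A biological loss and a weaker immunoprecipitation cannot be told apart here, because no array has an outside standard.

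The higher ratios of Tf2 in both mutants stay open. In the value table, without LOWESS, the smallest same-day difference was 0.12, and the Tf2 levels in wt are above 0 there and below 0 in the processed ratios. If brightness of multi-copy DNA were the source, mitochondrial probes would shift as much as Tf2. The Tf2 shift minus the mitochondrial shift was above 0 in 4 of 6 values: 0.87 and 0.92 (processed and value table) for rrp6Δ on day 1, and 0.40 and 0.50 for the double mutant. It was -0.49 and -0.27 for rrp6Δ on day 2. The pairs disagree in sign, and the double mutant and rrp6Δ on day 2 share 1 wt array, so the values do not decide on brightness. Fewer Tf2 copies in the mutants could lower Cy3, which differed by as much as -0.58 within a day, and no test here shows whether a copy change would cancel in the ratio. Dye effects, a change in copy number and a gain of the mark cannot be told apart for Tf2.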

How the results depend on the processing

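Of the choices below, list shifts from probes that match once were added after the data were seen. The 60 named gene differences kept their direction in all 1076 alternative values, and 145 of these passed the threshold; of 540 values for 32 list differences, 479 kept direction and side, 47 passed the threshold and 14 reversed. The named genes were picked for no overlap between groups, so leaving out a replicate could not reverse their direction. Other eBayes settings and fits of only the compared groups leave each difference unchanged. So does a block on scan day or replicate number in rrp6Δ against wt. The values from those settings therefore do not test the direction of the named genes. The cause of each shift was not tested unless given.

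Called genes, 0 in each comparison, numbered 19 for rrp6Δ against wt and 52 (16 higher) for the double mutant against wt with the replicate number as a block, and 19 and 30 with scan day. The labels do not say that the number marks a day, and the deviations of the numbered pairs correlated at 0.59 over 5078 genes. The double mutant against wt also gave 6 with mode centring, 5 in the value table and 35 with only the 2 groups fitted. Leaving out a replicate gave 0 to 78 genes and 0 to 1121 probes for rrp6Δ against wt, 0 to 35 and 0 to 227 for the double mutant against wt, and 0 to 476 probes between the mutants. Called probes numbered 395 for rrp6Δ with either block, and for the double mutant 247 (replicate), 169 (scan day) and 227 (2 groups). Called lists, 0 in the main setting, were 7 and 3 (rrp6Δ and double mutant against wt) with normexp, 7 and 2 with loess, 8 and 3 in the value table, 3 and 1 with unique probes, and 0 to 6 and 0 to 3 when a replicate was left out.

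Quantile normalization, which by construction gives all arrays 1 distribution, reversed centromeres 1, 2 and 3 to 0.22, 0.14 and 0.16 and the helicases to 0.13 in rrp6Δ against wt, and the centromeres between the mutants to -0.025, -0.027 and -0.046. Centromere 2 in rrp6Δ became 0.026 with unique probes, which may leave out much of the methylated DNA there. When a replicate was left out, the rRNA genes in rrp6Δ ranged from -0.74 to 0.19 (without replicate 1 of rrp6Δ). Mitochondrial DNA became -0.057 in the value table for rrp6Δ, and -0.052 with normexp and -0.15 in the value table for the double mutant; it ranged from -0.052 (without replicate 2 of wt) to 1.01 and from -0.20 (without replicate 2 of wt) to 0.86 when a replicate was left out. With unique probes subtelomere 2L in wt read -0.047, and 2R -0.015 in rrp6Δ and -0.15 in the double mutant.

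Lists at 0.5 or more in every array became 4, 1 and 3 (wt, rrp6Δ, double mutant) with unique probes; in rrp6Δ they became 9 with normexp and ranged from 4 to 5 when a replicate was left out. Domains in rrp6Δ, 0 in the main setting, were 25 at a threshold of 0.8, 25 on the mean of the arrays and 29 with normexp. The whole-cell-extract difference at rrp6 (mutants minus wt) was -2.19 in processed signal and -2.41 with normexp. The mutants lack that DNA, so the size of this difference depends on background signal and its treatment. The correlation of the mutants' changes was 0.62 with quantile normalization and 0.66 with normexp. The median signal was 979 to 1268 in Cy3 against 332 to 343 at the negative controls, and the background treatment changed the calls as given above; its limit was not compared with that of the 5 arrays.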

Other observations

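Strain marker genes differed between arrays in the whole-cell-extract channel. Relative to the array median (log2), leu1 was 0.96 and 0.20 in rrp6Δ, 0.07 in the double mutant and 0.28 and 0.09 in wt, and ade6 was 0.09 and -0.39 in rrp6Δ, -0.37 in the double mutant and -0.25 and -0.45 in wt. Both genes were highest in replicate 1 of rrp6Δ.

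Long non-coding RNA genes, tested in place of protein-coding genes after the data were seen, gave 0 calls by limma of 6444 in each comparison, with 248, 186 and 131 genes at an unadjusted p under 0.05 for rrp6Δ against wt, the double mutant against wt and the double mutant against rrp6Δ.

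Ribosomal protein genes, which are highly transcribed, had a mean ratio of -0.36 in replicate 1 of rrp6Δ and 0.17 in replicate 2, and -0.14 and 0.10 in replicates 1 and 2 of wt, so both strains were lower on day 1. Within days, rrp6Δ minus wt was -0.23 on day 1 and 0.07 on day 2.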
